A study of Mus musculus with 6 samples.

How the data were processed

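RNA-seq was performed on 6 libraries from C2C12 cells, an established mouse myoblast line: 3 labelled HA-NUR77 and 3 labelled GFP. Per the labels' protocols, each replicate was a separate dish of a stable line, doxycycline at 1 µg/mL was added 24 hours after seeding, and cells were lysed 18 hours later. Libraries were made from 1000 ng of total RNA with a stranded poly(A) kit based on dUTP and oligo-dT beads, with 12 PCR cycles. The deposited values are counts of reads per Ensembl gene, 1 table per library, not normalised. Per the submitters' processing notes, the tools named were TopHat2 2.1, HTSeq and DESeq2, and the genome build was mm10. The gene annotation release, the strand setting of the counting and the role of DESeq2 were not given in the sources used here.

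The 6 tables held the same 23154 gene IDs in the same order, with no summary lines, and 3275 genes had no read in any library. Symbols were matched through the GENCODE M21 gene names for 22872 IDs, and the other 282 kept their Ensembl ID. Coordinates, exon lengths (the union of annotated exons) and GC content came from the same GENCODE release, which is on GRCm38, the assembly that mm10 denotes. Totals ran from 13906096 counts in HA-NUR77 replicate 3 to 22821446 in HA-NUR77 replicate 2, with 16797515, 14626157 and 14980546 in GFP replicates 1, 2 and 3 and 19248468 in HA-NUR77 replicate 1. No column of per-sample values was left unused. Reads of near-identical sequence, such as those of processed pseudogenes, nuclear copies of mitochondrial genes and granzyme paralogs, can be lost or split in such counting, and genes of these kinds are reported as uncertain.

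The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors and group as the only term, on genes kept by filterByExpr with its minimum count of 10. It used robust fitting, and p-values were adjusted by the Benjamini-Hochberg method over the 12509 genes kept, with a threshold of 0.05. Values per group are counts scaled by library total and TMM factor (CPM), as mean ± SD over 3 libraries, and fold changes are the fitted ones with their standard error (SE). For genes with few reads a depth-scaled ratio is given with an exact binomial 95% interval, which covers counting error only. It divides the reads summed over each group by that group's summed counts in tested genes, without TMM factors. Lists were tested two-sided with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 22 pathway lists, then again with the correlation estimated from the data and with fry, a self-contained test of whether the members move on balance in 1 direction.

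The design, the test, the alternatives, the 22 pathway lists, the 7 lists of markers of other cell types and the rule for named genes were set before the data were examined. The rule named Nr4a1, Nr4a2, Nr4a3, Yy1 and Ppargc1a. To these it added the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out predicted and pseudogene models. Of each pathway list it took the 3 members with the smallest adjusted p, or the most abundant member where none passed, and of each cell type list the most abundant member and up to 2 past the threshold. Where 5 or fewer members of a list changed in a direction, the others are also named, apart from 1 OXPHOS subunit, with some members whose call the block changes, and these were chosen after their values were seen.

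The labels give both groups the replicate numbers 1 to 3 without saying that a number marks a shared day. Whether the numbers pair the libraries was checked on the deviations of log2 CPM from the group means, before the fits were compared. Deviations of same-numbered libraries correlated across genes at 0.25 for number 1, 0.55 for number 2 and 0.47 for number 3, each over the 0.1 set for a pairing, so the pairing comes from the data and not from a label. With 3 libraries per group there are few ways to match them, and many genes do not add replicates. A match by chance is therefore not excluded, and the pairing is an assumption of the blocked fit. A fit with the replicate number as a block, which leaves 2 residual degrees of freedom in place of 4, is therefore given beside each call that it changes and each count that it moves by over 1.5 times. Within a group, no pair of libraries agreed within sampling noise, since the smallest chi-square per degree of freedom was 10.9, and each library counts as 1 replicate.

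The fits were tested on simulated data drawn from the means, dispersions and library sizes of these 6 libraries, with 200 of 12509 genes changed. The test without a block made 168 calls, of which 7.74% were false, and recovered 46% of genes changed by a log2 of 0.5, 78% at 0.75, 86% at 1 and 100% at 2. With a shared replicate effect simulated, the fit with the block recovered 76% at a log2 of 1 and the fit without it 22%, with 12.3% and 3.28% false calls. That effect was added to dispersions of the fit without a block, which already hold any shared variation, so it was counted 2 times. These rates do not carry over to the real libraries. There the block moved the genes at least 2-fold higher from 270 to 320 and those lower from 462 to 513. DESeq2 gave 19% false calls on the same simulated counts. Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters, Nr4a1 left out of the totals, fitting without robustness, a stricter threshold, the block and leaving out each library. Correction of each library for exon length and GC content, with and without the block, and thinning of all libraries to the smallest total were added after seeing the data.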

Results

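Gene expression was measured by RNA-seq in C2C12 mouse myoblasts, muscle precursor cells that fuse into myotubes when serum is withdrawn. The cells were stable lines carrying a doxycycline-inducible construct for HA-tagged NUR77, the orphan nuclear receptor encoded by Nr4a1, or for GFP as the control. There were 3 libraries per construct, each from its own dish, collected after 18 hours of doxycycline at 1 µg/mL, with 13906096 to 22821446 counts per library. The comparison asks which transcripts differ after induction of NUR77, in a series whose title concerns NUR77, the transcription factor YY1 and the abundance and activity of mitochondria in macrophages. The labels name 1 stable line per construct, so any difference between the lines themselves enters the same comparison as the construct.

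The transcript of Nr4a1, the mouse gene for NUR77, did not pass the test of a difference between the groups. Mouse Nr4a1 (ENSMUSG00000023034; GRCm38 chromosome 15, 101254269 to 101274795, plus strand) had 437, 445 and 355 reads in the libraries labelled HA-NUR77 and 327, 196 and 417 in those labelled GFP. Its level was 22.5 ± 3.03 CPM against 20.4 ± 7.43 CPM (SD, n = 3), a log2 fold change of 0.14 (SE 0.24, edgeR adjusted p = 0.698), and the upper 95% bound of the change was 1.64-fold. The direction rested on GFP replicate 2, without which the log2 fold change was −0.08. The species of the NUR77 insert is not given in the sources used here, and reads of a construct that differs from the mouse gene would not all be counted there. Nr4a1 therefore does not check the labels, and the directions below are those of the libraries labelled HA-NUR77. The related receptors Nr4a2 (log2 fold change −0.25, SE 0.28) and Nr4a3 (−0.12, SE 0.30) did not pass the test, with edgeR adjusted p of 0.541 and 0.812. Yy1 stood at 57.8 ± 0.833 CPM against 55.1 ± 3.28 CPM (log2 fold change 0.07, SE 0.07, adjusted p = 0.488). Ppargc1a, which encodes the mitochondrial coactivator PGC-1α, stood at 4.86 ± 1.46 against 5.35 ± 1.16 CPM (−0.16, SE 0.26, adjusted p = 0.68). None of the 3 members of the NR4A list passed by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05; the camera adjusted p was 0.953.

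**Figure D1:**
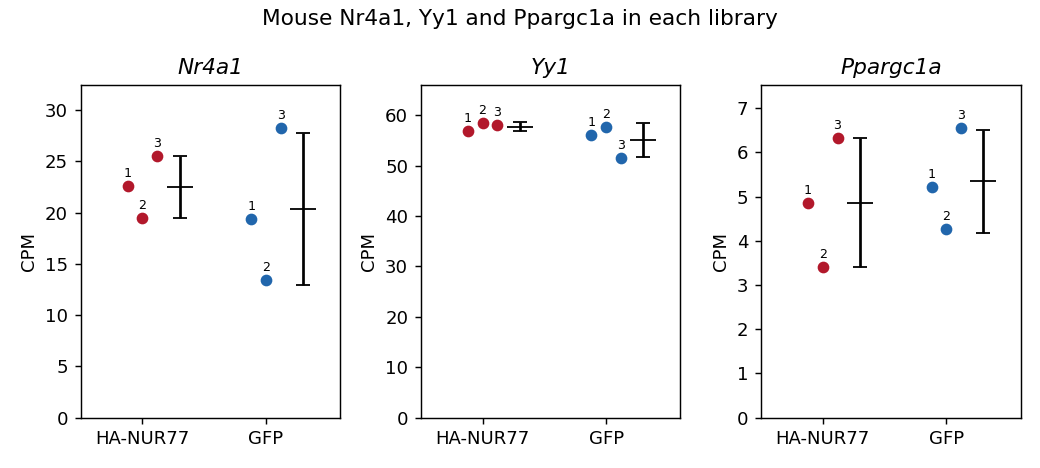
Level of mouse Nr4a1, Yy1 and Ppargc1a in CPM (linear axes from 0) in each of the 3 libraries per group, numbered by replicate, with the mean and SD beside them. Nr4a1 lies at 22.5 ± 3.03 CPM in the libraries labelled HA-NUR77 and 20.4 ± 7.43 CPM in those labelled GFP, and the groups overlap.

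A large share of the transcriptome differed all the same. Of 12509 genes tested, 1549 were higher and 1655 lower in the libraries labelled HA-NUR77, and 270 and 462 of these changed at least 2-fold. Counts of called members in the lists below are to be read against these shares over all genes. For the NR4A, mtDNA, mitochondrial biogenesis, cholesterol, cell cycle, stress response and clock lists, a smaller share of members was called than of all genes. Among genes with a mean of at least 5 CPM in the higher group, the largest rises were in Gzme and Gzmd, cytotoxic granzymes that were almost silent in the GFP libraries, and the largest falls in Col8a2, a collagen of basement membranes, and Gng2, a G protein gamma subunit. With the replicate number as a block, 2942 genes were higher and 3071 lower, and 3196 of the 3204 genes called without the block were called with it in the same direction. There were 672 higher and 903 lower without HA-NUR77 replicate 1, 642 and 850 without GFP replicate 1, and 927 higher without GFP replicate 2. Of all genes tested, 5700 had no overlap between the groups, a separation that chance gives to 10% of genes if all libraries are exchangeable. Same-numbered libraries deviated together, so that share may differ here.

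Gzme (chromosome 14, 56117626 to 56120625) had 838 reads over the HA-NUR77 libraries and 3 over the GFP libraries, a depth-scaled ratio of 232 (95% interval 79 to 1125; edgeR adjusted p = 9.51e-05). Gzmd, its neighbour on the same strand, had 441 and 2 reads, a ratio of 183 (50.3 to 1514; adjusted p = 0.00026). These paralogs lie in a cluster of closely similar genes, so the split of reads between them is uncertain. The GFP reads of Gzmd were all in replicate 1, and the fitted log2 fold change of Gzme was 7.68, or 8.58 without GFP replicate 2. Further rises were in Oas2, an interferon-induced antiviral enzyme (log2 fold change 3.86, SE 0.70; 3.16 without HA-NUR77 replicate 2), Cdsn, which encodes corneodesmosin (3.53, SE 0.24), Dhrs9, a retinol dehydrogenase (3.45, SE 0.33), the interferon-responsive gene Ifi27l2a (3.30, SE 0.46), Lman1l (3.03, SE 0.24) and the complement inhibitor Serping1 (2.98, SE 0.20), with edgeR adjusted p from 0.000187 to 0.00857. Col8a2 (chromosome 4, 126286793 to 126314330) went from 51.3 ± 2.84 CPM in GFP to 1.61 ± 0.612 CPM (SD, n = 3), a 30.6-fold fall (adjusted p = 4.11e-05). Gng2 fell 16.9-fold, the chemokine scavenging receptor Ackr4 15.3-fold, the metalloprotease Adamts17 13.7-fold, the connexin Gja5 13.3-fold and the WNT-inactivating protease Trabd2b 13.1-fold. The T-type calcium channel Cacna1g fell 12.2-fold and Gli2, a transcription factor of hedgehog signalling, 10.3-fold. Adjusted p for the 8 falls ran from 4.11e-05 to 0.000447.

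**Figure D2:**
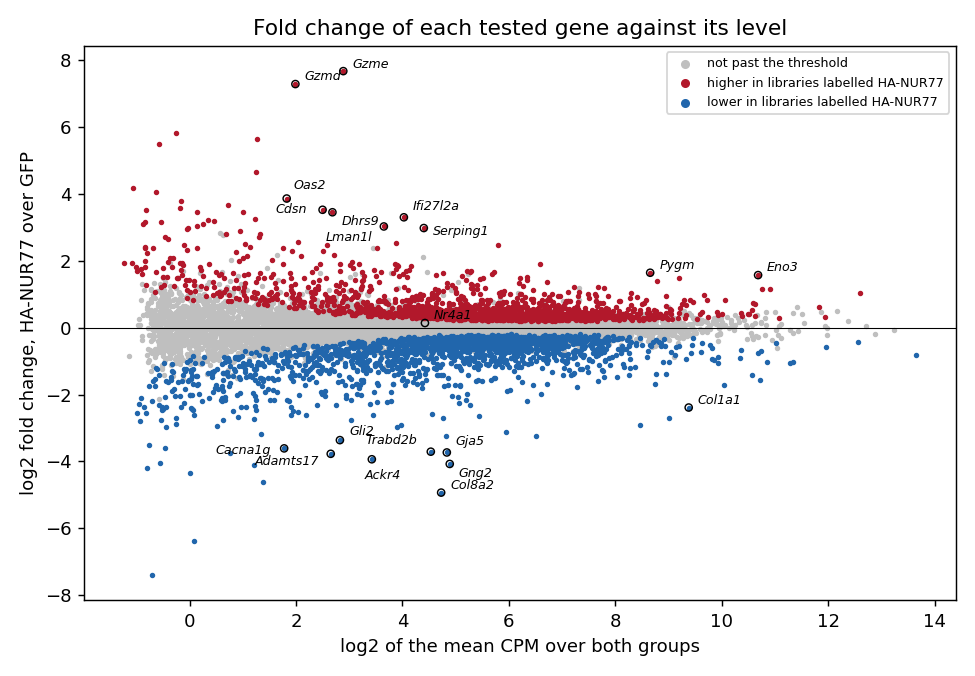
Fitted log2 fold change of HA-NUR77 over GFP for each of the 12509 genes tested, against log2 of the mean CPM over both groups, with genes past the adjusted p threshold in red (1549 higher) or blue (1655 lower) and the others in grey. The 8 largest rises and falls by the naming rule are labelled with Nr4a1, Col1a1, Pygm and Eno3, and Gzme and Gzmd lie above all other genes.

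Many nuclear genes for subunits of the respiratory chain rose by a small amount, while the transcripts of the mitochondrial genome itself did not pass the test. Of 76 OXPHOS subunits measured, 52 rose, 1 fell and 23 did not pass, and the median change was 1.26-fold (log2 0.33). Uqcr10, a subunit of complex III, rose from 42.3 ± 2.53 to 67.6 ± 2.92 CPM (SD, n = 3; edgeR adjusted p = 0.00113), Atp5e, of ATP synthase, from 52.7 ± 4.52 to 82.4 ± 5.76 CPM (adjusted p = 0.00271) and Cox6c, of cytochrome c oxidase, from 116 ± 2.52 to 154 ± 4.67 CPM (adjusted p = 0.00406). Adjusted over the list alone, 67 rose and 1 fell. These transcripts are short, and fold changes fell with transcript length over all genes; with correction for length and GC content 35 rose, with a median log2 fold change of 0.23. The camera adjusted p was 2.83e-14 at the preset correlation, but adjusted p = 0.65 with an estimated correlation, and none of the 11 lists past the threshold at the preset held with it; fry gave 0.0177. Subunits higher numbered 25 without HA-NUR77 replicate 1, 30 without HA-NUR77 replicate 3, 20 without GFP replicate 1 and 26 without GFP replicate 2, and the 1 fall was not past the threshold in these fits. Another grouping of the libraries, HA-NUR77 1 with GFP 1 and 2, gave a camera p of 2.99e-16 for this list, against 3.86e-15 for the labelled groups, with 0 genes called by edgeR and 296 at an unadjusted p under 0.05. The list's median level, relative to the GFP mean on the log2 scale, was 0.31, −0.07 and −0.03 in those libraries. It was 0.28, 0.41 and 0.11 in HA-NUR77 2, HA-NUR77 3 and GFP 3, so that grouping holds part of the difference between constructs.

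In 3 further lists of nuclear genes for mitochondria, more members rose than fell, and most did not pass. Of 75 mitochondrial ribosomal proteins, 23 rose and 52 did not pass (28 rose adjusted over the list alone), among them Mrpl30 (log2 fold change 0.43, SE 0.07), Mrps31 (0.51, SE 0.09) and Mrps24 (0.44, SE 0.08), with edgeR adjusted p of 0.00617, 0.00663 and 0.00858. Of 36 genes of mitochondrial dynamics, import and mitophagy, 17 rose and 19 did not pass (24 rose adjusted over the list alone). They included the fission adaptor Fis1 (1.44-fold), the cristae protein Chchd3 (1.33-fold) and prohibitin Phb (1.47-fold). Of 28 TCA cycle genes, 9 rose and 2 fell (14 and 2 adjusted over the list alone): Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose 1.63-fold, Suclg1, of succinyl-CoA ligase, 1.38-fold and Idh3g, of isocitrate dehydrogenase, 1.38-fold, while Pcx (log2 fold change −0.59, SE 0.14) and Pdk4 (−0.30, SE 0.09) fell. Camera gave adjusted p of 4.97e-06, 9.43e-06 and 0.00125 for these lists in that order, and adjusted p = 0.65, 0.388 and 0.653 with an estimated correlation, and fry gave 0.0162, 0.00607 and 0.0291. With correction for length and GC content, 14 mitochondrial ribosomal proteins were higher. With the block the members higher numbered 39, 28 and 17, and in the second list Yme1l1 (log2 fold change −0.21) and Dnm1l (−0.19) were lower (adjusted p = 0.0196 and 0.0296 with the block; 0.279 and 0.413 without it). Without GFP replicate 1 they numbered 7, 10 and 5, without HA-NUR77 replicate 1 the first 2 lists had 10 and 10, and the first had 14 without HA-NUR77 replicate 3 and 9 without GFP replicate 2. TCA members lower numbered 0 without HA-NUR77 replicate 1 or GFP replicate 1 and 1 without HA-NUR77 replicate 2, GFP replicate 2 or GFP replicate 3, with library totals only, upper-quartile factors or thinned counts.

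Of the 10 measured mtDNA-encoded genes, 0 rose and 0 fell by edgeR, with 0 at an unadjusted p under 0.05, and DESeq2 called 1 lower and limma-voom 0. The most abundant, mt-Co1, stood at 9499 ± 1111 CPM in the libraries labelled HA-NUR77 and 9882 ± 792 CPM in GFP (log2 fold change −0.06, SE 0.13, adjusted p = 0.764), and the share of all counts on mitochondrial transcripts ran from 2.93% to 3.48% and from 3.19% to 3.68%. By replicate number the share was 3.29%, 2.93% and 3.48% in HA-NUR77, each lower than the 3.34%, 3.19% and 3.68% in GFP. With the block, 3 fell. These were mt-Nd5, mt-Atp8 and mt-Cytb (edgeR adjusted p = 0.0117, 0.00385 and 0.0348 with the block). Reads of mt-Co2, mt-Co3, mt-Atp6 and mt-Nd3 were nearly absent, so this list covers the mitochondrial genome in part and is uncertain. Camera gave it an adjusted p of 0.613, and 0.937 with an estimated correlation. Among 29 genes of mitochondrial biogenesis and mtDNA maintenance, 4 rose and 3 fell, also adjusted over the list alone, and 8 and 6 with the block. Tfam, which packages mtDNA and helps start its transcription, rose 1.36-fold (adjusted p = 0.0174) and the nuclear receptor Esrra 1.31-fold (adjusted p = 0.0192), with Ppargc1b (log2 fold change 0.43) and Polrmt (0.28). The receptor Esrrb had 6 reads against 62, a ratio of 12.5 in favour of GFP (95% interval 5.41 to 35.3; adjusted p = 0.00512; fitted log2 fold change −3.59, or −4.33 without HA-NUR77 replicate 2), and Gabpb1 (−0.29) and Ppard (−0.24) fell. The list's median was −0.02 and its mean −0.06, although camera placed it upward with an adjusted p of 0.821. The rises of Tfam and Esrra lost the threshold without HA-NUR77 replicate 1, GFP replicate 1 or GFP replicate 2, and that of Esrra also without HA-NUR77 replicate 3, with adjusted p of 0.051 to 0.0722. Leaving out HA-NUR77 replicate 1, GFP replicate 1 or GFP replicate 2 left 0 of these genes higher, leaving out HA-NUR77 replicate 3 left 1, and leaving out any of these or GFP replicate 3 left 1 lower.

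**Figure D3:**
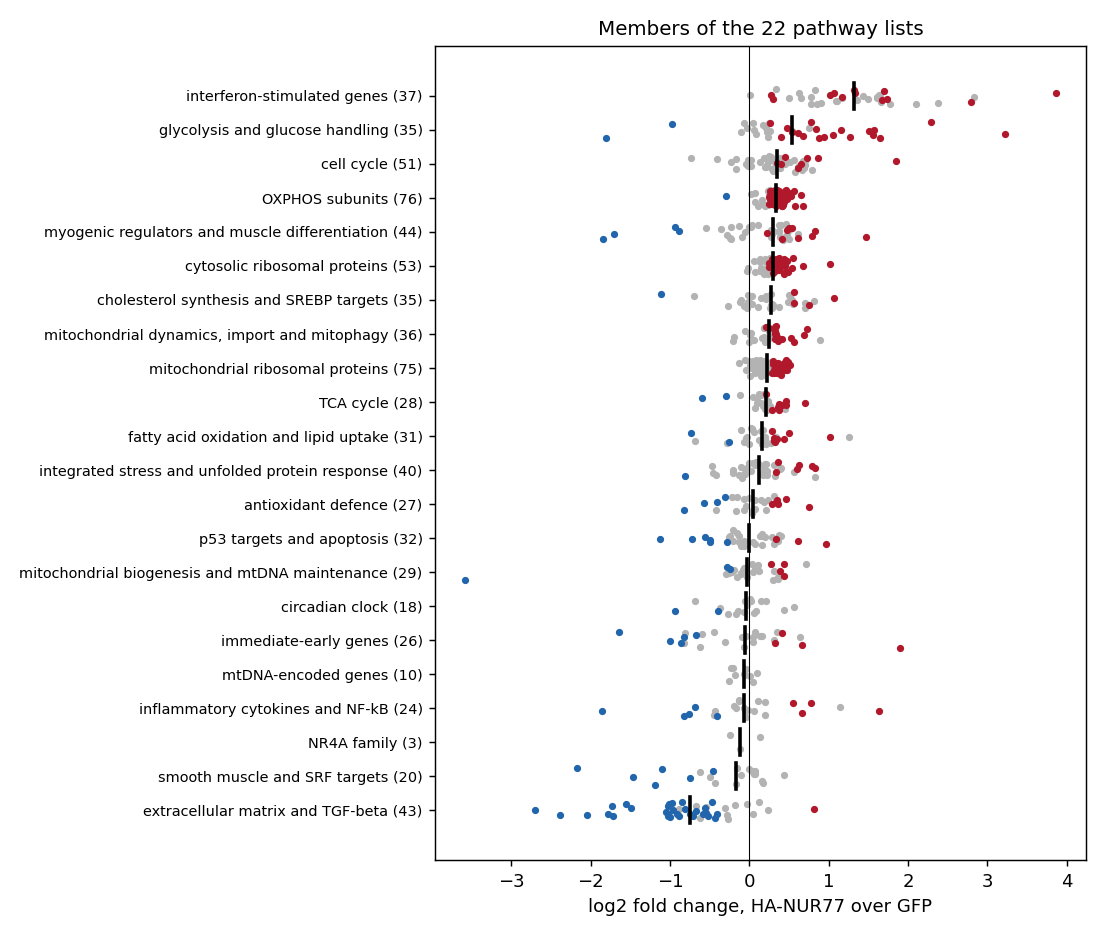
Fitted log2 fold change of HA-NUR77 over GFP for the tested members of the 22 pathway lists, with the number tested in brackets, the median as a black bar, members past the adjusted p threshold in red (higher) or blue (lower) and the others in grey. Interferon-stimulated genes have the highest median, 1.32, and extracellular matrix genes the lowest, −0.75.

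Most changes among genes of glycolysis and glycogen breakdown were rises. Of 35 genes measured, 19 rose, 2 fell and 14 did not pass (21 and 2 adjusted over the list alone), with a median change of 1.45-fold. Pygm, muscle glycogen phosphorylase (chromosome 19, 6384399 to 6398459), rose from 195 ± 22.5 to 610 ± 35 CPM (SD, n = 3; edgeR adjusted p = 0.000122), Phka1, a regulatory subunit of its activating kinase, from 42.4 ± 3.23 to 120 ± 2.07 CPM (adjusted p = 6.93e-05) and Eno3, muscle enolase, from 827 ± 101 to 2460 ± 86.3 CPM (adjusted p = 0.000219). The glucose transporter Slc2a3 (log2 fold change −1.81, SE 0.28) and the glycolytic regulator Pfkfb3 (−0.98, SE 0.19) fell. Camera gave an adjusted p of 2.29e-15, and adjusted p = 0.15 with an estimated correlation (0.0068 before adjustment); fry gave 0.00166.

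Genes of fat use, redox defence and sterol synthesis changed in both directions. Of 31 genes of fatty acid oxidation and lipid uptake, 8 rose and 2 fell (8 and 3 adjusted over the list alone, 16 and 4 with the block). Acsl1, which activates long-chain fatty acids, rose 2.03-fold, the carnitine carrier Slc25a20 1.41-fold and the acyl-CoA dehydrogenase Acadvl 1.35-fold, with edgeR adjusted p of 0.00566, 0.00538 and 0.0077, while Ucp2 (log2 fold change −0.26) and Cd36 (−0.74) fell. Its camera adjusted p was 0.0511, past the threshold (0.019 to 0.0494) with library totals only, upper-quartile factors, other filters, limma-voom or thinned counts and without HA-NUR77 replicate 2, GFP replicate 1 or GFP replicate 3, and adjusted p = 0.65 with an estimated correlation; fry gave 0.0209. Without HA-NUR77 replicate 1, HA-NUR77 replicate 3 or GFP replicate 1 there were 4, 5 or 3 higher, and members lower numbered 0 or 1 in each fit without 1 library. Of 27 antioxidant genes, 6 rose and 4 fell, also adjusted over the list alone, and 10 and 7 with the block. The mitochondrial proteins Prdx5 (1.68-fold, adjusted p = 0.000489) and Txn2 (1.37-fold, adjusted p = 0.00515) rose, and Gclc, which makes the glutathione precursor, fell 1.49-fold (adjusted p = 0.00225), as did Hmox1 (−0.41), Sod3 (−0.82) and Gpx8 (−0.30). That list's camera adjusted p was 0.526 and fry gave 0.0399, or 0.0814 with the block, and 3 members were higher without HA-NUR77 replicate 1 and 2 without HA-NUR77 replicate 3, GFP replicate 1 or GFP replicate 2. Of 35 genes of cholesterol synthesis and SREBP targets, 4 rose and 1 fell (4 rose adjusted over the list alone; 15 and 3 with the block): Acss2, an acetyl-CoA synthetase, 2.09-fold, Insig2 1.48-fold, the desaturase Scd1 1.68-fold and Pmvk by a log2 of 0.56, against Abca1 (−1.12). DESeq2 called 7 higher. Camera gave this list an adjusted p of 0.0255, and adjusted p = 0.812 with an estimated correlation (fry 0.346), and the call was lost without HA-NUR77 replicate 2 (0.361), GFP replicate 1 (0.0825) or GFP replicate 3 (0.0626). Its median level, relative to the GFP mean on the log2 scale, overlapped between the groups. This level was 0.28, 0.55 and −0.17 in HA-NUR77 replicates 1, 2 and 3, and −0.22, 0.34 and −0.11 in GFP replicates 1, 2 and 3. Members higher numbered 9 without HA-NUR77 replicate 3 and 7 without GFP replicate 2, and Abca1 was not past the threshold with no filter or without HA-NUR77 replicate 1, HA-NUR77 replicate 2, GFP replicate 1 or GFP replicate 3.

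Most collagen and other matrix genes of the list fell. Of 43 genes of the extracellular matrix and TGF-beta response, 30 fell, 1 rose and 12 did not pass (34 and 1 adjusted over the list alone; 37 and 2 with the block), with a median log2 fold change of −0.75. Col1a1, the main fibrillar collagen (chromosome 11, 94936224 to 94953042), stood at 1118 ± 43.3 CPM in GFP and 213 ± 33.6 CPM in the libraries labelled HA-NUR77 (SD, n = 3), a 5.24-fold fall (edgeR adjusted p = 7.76e-05). Thbs1, thrombospondin, fell 2.94-fold (adjusted p = 0.000326) and Col11a1 4.14-fold (adjusted p = 0.00038), and the 1 gene that rose was Ltbp1, a binding protein of latent TGF-beta (log2 fold change 0.82, SE 0.14), joined with the block by Mmp2 (0.23; adjusted p = 0.171, 0.0494 with the block). Among 20 smooth muscle and SRF target genes, 6 fell and 0 rose by edgeR (7 and 1 adjusted over the list alone; 11 and 2 with the block), with 1 higher at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Those that fell included Lmod1 (2.14-fold, adjusted p = 0.00473), Tagln (2.28-fold, adjusted p = 0.0059) and Actg2 (2.77-fold, adjusted p = 0.00657). Camera gave an adjusted p of 2.51e-21 for the matrix list and 0.0335 for the SRF list, and adjusted p = 0.398 and 0.766 with an estimated correlation, and fry gave 0.0144 and 0.157. The SRF call was lost without HA-NUR77 replicate 3 (0.0949) or GFP replicate 2 (0.0913); 1 SRF gene was higher without GFP replicate 3, with upper-quartile factors or with no filter, and 2 matrix genes were higher without GFP replicate 1.

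Muscle genes moved both ways. Of 44 myogenic and muscle differentiation genes, 9 rose and 4 fell (11 and 4 adjusted over the list alone), and 27 rose and 9 fell with the block. DESeq2 called 18 higher and 5 lower. Myoglobin, Mb, rose from 311 ± 75.4 to 864 ± 164 CPM (SD, n = 3; edgeR adjusted p = 0.00337) and the perinatal myosin Myh8 1.73-fold (adjusted p = 0.00331). Caveolin Cav3, of the muscle membrane, fell 3.25-fold (adjusted p = 0.000242), along with the adult fast myosins Myh1 (log2 fold change −0.93) and Myh2 (−0.88) and the regulator Myf6 (−1.84). For the list, camera gave an adjusted p of 0.058 without the block and 0.00151 with it, and adjusted p = 0.811 and 0.571 with an estimated correlation, and fry gave 0.318. It was also past the threshold without HA-NUR77 replicate 1 (0.0241), HA-NUR77 replicate 2 (0.028) or GFP replicate 3 (0.000773), and with limma-voom (0.0311) or other filters (0.019 and 0.0379). Members higher numbered 4 without HA-NUR77 replicate 1 or GFP replicate 1, 3 without HA-NUR77 replicate 3, 5 without GFP replicate 2 and 20 without GFP replicate 3.

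Cyclins and replication genes were higher in part. Of 51 cell cycle genes, 8 rose and 43 did not pass, with 2 higher adjusted over the list alone and 27 higher and 2 lower with the block. The list's median level, relative to the GFP mean on the log2 scale, overlapped between the groups. It was 0.22, 0.61 and 0.30 in HA-NUR77 replicates 1, 2 and 3, and −0.15, 0.41 and −0.33 in GFP replicates 1, 2 and 3. Cyclin D1, Ccnd1, rose from 6.62 ± 1.46 to 23.7 ± 6.79 CPM (SD, n = 3; edgeR adjusted p = 0.00268), Ccnd2 1.66-fold (adjusted p = 0.00999) and the replication factor Cdc45 1.57-fold (adjusted p = 0.0223). The call of Cdc45 was lost without HA-NUR77 replicate 1 (0.0715), HA-NUR77 replicate 3 (0.0517), GFP replicate 1 (0.067) or GFP replicate 2 (0.0648). Camera gave an adjusted p of 0.00344 and adjusted p = 0.811 with an estimated correlation, and fry gave 0.276. Without HA-NUR77 replicate 2 or GFP replicate 3 the camera adjusted p was 0.0618 or 0.0591. Leaving out GFP replicate 2 gave 13 higher, and leaving out HA-NUR77 replicate 1 or GFP replicate 1 gave 2. Without HA-NUR77 replicate 2 there were 3 higher and 1 lower, without GFP replicate 3 there were 4 higher and without HA-NUR77 replicate 3 there were 5. Among 32 p53 targets and apoptosis genes, 3 rose and 6 fell (6 and 6 adjusted over the list alone, 11 and 10 with the block; camera adjusted p = 0.953). The death receptor Fas fell 2.18-fold (adjusted p = 0.00246) and the BH3-only gene Bcl2l11 1.65-fold (adjusted p = 0.00373), while Bid rose 1.53-fold (adjusted p = 0.0071), with Mcl1 (log2 fold change 0.33) and Bik (0.97). Without HA-NUR77 replicate 1 or GFP replicate 1 there was 1 of these genes higher, and without GFP replicate 1 or GFP replicate 2 there were 3 lower; with upper-quartile factors or no filter 6 were higher.

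The median level of interferon-stimulated genes was higher in HA-NUR77 replicates 1 and 2 and close to the GFP level in replicate 3. Of 37 genes measured, 12 rose and 25 did not pass (26 rose adjusted over the list alone), with a median log2 fold change of 1.32. Of the 37, DESeq2 called 20 higher and limma-voom 10, and edgeR without a filter called 7. Ifi27 rose 2.02-fold (edgeR adjusted p = 0.0025), Ifi35 2.5-fold (adjusted p = 0.0054) and Bst2, which tethers budding virus, 3.23-fold (adjusted p = 0.00751; 0.108 with the block). Xaf1 (log2 fold change 1.32) and Rtp4 (1.67) also rose without the block, with adjusted p of 0.099 and 0.214 with it. In HA-NUR77 replicate 3, Ifi27, Ifi35 and Bst2 stood at 152, 47.5 and 37.3 CPM, against GFP means of 67.3, 22.5 and 18.6 CPM. The list's median level, relative to the GFP mean on the log2 scale, was 1.40, 1.67 and 0.17 in HA-NUR77 replicates 1, 2 and 3, and −0.55, 0.39 and 0.14 in GFP replicates 1, 2 and 3. Camera gave an adjusted p of 1.14e-07 and adjusted p = 0.708 with an estimated correlation, and fry gave 0.145. Without HA-NUR77 replicate 3, 35 members were higher, and without HA-NUR77 replicate 1, HA-NUR77 replicate 2, GFP replicate 1 or GFP replicate 3 the number was 5, 7, 6 or 7.

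**Figure D4:**
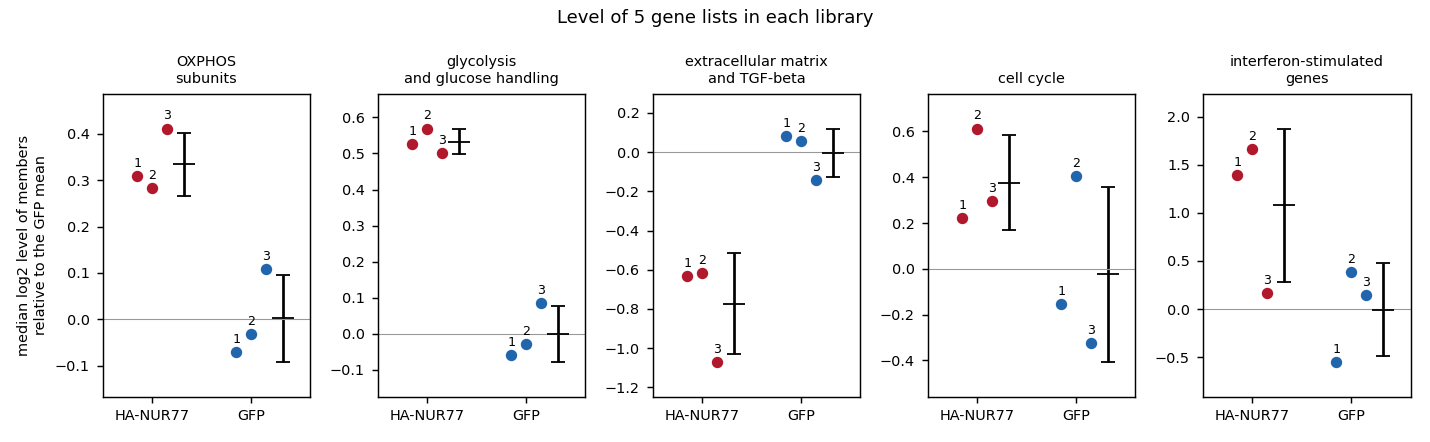
Median log2 level of the members of 5 gene lists in each library relative to the mean of the GFP libraries, numbered by replicate, with the mean and SD of the 3 libraries per group beside them. For OXPHOS subunits, glycolysis and extracellular matrix the groups separate, while interferon-stimulated genes stand at 1.40 and 1.67 in HA-NUR77 replicates 1 and 2 and at 0.17 in replicate 3.

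Signalling lists moved in both directions. Of 24 measured genes of inflammatory cytokines and NF-kB, 4 rose and 5 fell, also adjusted over the list alone. Ptgs2, cyclooxygenase 2, fell 3.62-fold (edgeR adjusted p = 0.000156), the receptor Tlr2 1.76-fold and the macrophage growth factor Csf1 1.6-fold, with Cx3cl1 (log2 fold change −0.41) and Lif (−0.76), while Tnfaip2 (0.54) and the chemokines Ccl2 (0.66), Ccl7 (0.77) and Ccl8 (1.63) rose. Members higher numbered 1 without HA-NUR77 replicate 1 or GFP replicate 2 and 2 without HA-NUR77 replicate 2, GFP replicate 1 or GFP replicate 3, and members lower 3 without HA-NUR77 replicate 1, HA-NUR77 replicate 3, GFP replicate 2 or GFP replicate 3. Camera gave an adjusted p of 0.356 and fry 0.031, or 0.118 with the block.

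Immediate-early and stress response genes were mixed as well. Of 26 immediate-early genes, 4 rose and 5 fell, also adjusted over the list alone, and 6 and 11 with the block. Egr3 fell 3.14-fold (adjusted p = 0.00153) and Junb 1.6-fold (adjusted p = 0.00226), with Egr2 (12.4 ± 3.54 against 25 ± 3.12 CPM; SD, n = 3), Ier5 (−0.82) and Fosb (−0.86), while Atf3 rose 3.73-fold (adjusted p = 0.00512), with Dusp4 (0.66), Klf2 (0.32) and Jun (0.41). Without GFP replicate 1 there was 1 higher and 2 lower, without HA-NUR77 replicate 1 there were 2 and 3, without HA-NUR77 replicate 2 there were 2 and 8, and without GFP replicate 3 there were 2 higher. Of 40 genes of the integrated stress and unfolded protein response, 6 rose and 1 fell, also adjusted over the list alone, and 17 and 5 with the block: Herpud1, of ER-associated degradation, 1.73-fold and the serine synthesis enzyme Psat1 1.52-fold, against Nupr1, which fell 1.75-fold (adjusted p = 0.00228, 0.00817 and 0.00144). That list had 3 higher without HA-NUR77 replicate 1 or GFP replicate 1 and 2 lower without HA-NUR77 replicate 1, and a camera adjusted p of 0.177, or 0.0144 without GFP replicate 2. Of 18 clock genes, Rora fell 1.92-fold (adjusted p = 0.0165) and Bhlhe41 1.31-fold (adjusted p = 0.0239), which were also the 2 adjusted over the list alone. No clock gene was higher by edgeR, DESeq2 or limma-voom (0 at an unadjusted p under 0.05), while 1 rose and 5 fell with the block; 1 was lower without HA-NUR77 replicate 1, HA-NUR77 replicate 3 or GFP replicate 2 and 0 without GFP replicate 1. Bhlhe41 kept the threshold without GFP replicate 3 alone among these fits, and Rora in all but that without GFP replicate 1 (0.0642). Camera gave 0.526 for the immediate-early list and 0.591 for the clock list.

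Cytosolic ribosomal proteins, a list of abundant housekeeping genes, were higher in part. Of 53 measured, 31 rose and 22 did not pass (40 rose adjusted over the list alone), with a median change of 1.23-fold, among them Rpl24 (2.03-fold), Rpl27 (1.6-fold) and Rpl26 (1.39-fold), with edgeR adjusted p of 0.000427, 0.000537 and 0.00215. Camera gave an adjusted p of 7.58e-12 and adjusted p = 0.65 with an estimated correlation, fry gave 0.0162, and 19 were higher without HA-NUR77 replicate 1. Processed pseudogenes of these genes make their counts uncertain. Across all genes tested, the fold change fell with the length of the transcript, from a median log2 of 0.18 in the tenth with the shortest exons to −0.18 in the tenth with the longest, and OXPHOS and ribosomal protein transcripts are short. With correction for length and GC content, 22 cytosolic ribosomal proteins, 3 antioxidant genes and 2 inflammatory genes were higher. With it 1 biogenesis gene, 1 fatty acid gene and 3 stress response genes were lower, and the fall of Abca1 was not past the threshold.

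Markers of other cell types were mostly below the expression filter, and those measured moved both ways. Of 8 fibroblast markers, Pdgfrb fell 2.14-fold (edgeR adjusted p = 0.00368) and Pdgfra 1.97-fold (adjusted p = 0.00085), with Pi16 (log2 fold change −0.57), while Ly6a, the stem cell antigen Sca-1, rose 2.32-fold (adjusted p = 0.00133), with Dpt (1.05 ± 0.0219 against 0.36 ± 0.151 CPM; SD, n = 3) and Cd34 (log2 fold change 0.82). Neuronal Nefl rose 5.71-fold at a low level (3.47 ± 0.962 against 0.615 ± 0.176 CPM; SD, n = 3; adjusted p = 0.00213), Tubb3 1.64-fold (adjusted p = 0.0285) and Map2 1.48-fold (adjusted p = 0.0251), of 4 measured. The skeletal markers Spp1 (1.77-fold, adjusted p = 0.0153) and Sox9 (1.23-fold, adjusted p = 0.0128) rose, of 3 measured; the other, Runx2, had a log2 fold change of −0.30 (adjusted p = 0.0888; 0.031 adjusted over the list alone and 0.00632 with the block). Of 2 adipocyte markers, Cebpa fell 2.12-fold (adjusted p = 0.0159) and Pparg rose 1.71-fold (adjusted p = 0.0362). Epithelial Krt14 fell 3.8-fold (adjusted p = 0.00153) and Cdh1 2.34-fold (adjusted p = 0.0112), and Krt19 stood at 9.78 ± 0.139 against 6.02 ± 2.45 CPM (adjusted p = 0.0905; 0.019 with the block). Endothelial Cldn5 had 58 reads against 17, a ratio of 2.83 (95% interval 1.62 to 5.18; adjusted p = 0.0733; 0.0068 with the block). Of 12 macrophage markers, 3 passed the filter: Csf1r rose from 19 to 78 reads (ratio 3.4, 95% interval 2.04 to 5.95; adjusted p = 0.0443), and the most abundant, Cd14, stood at 3.01 ± 0.787 against 2.31 ± 0.616 CPM (adjusted p = 0.311). Of the 6 fits that left out 1 library, Csf1r lost the threshold in 4, all but those without HA-NUR77 replicate 3 or GFP replicate 2, and Pparg in 5, all but that without HA-NUR77 replicate 2. Map2 lost it in 4, all but those without HA-NUR77 replicate 2 or GFP replicate 3, Tubb3 without HA-NUR77 replicate 1, HA-NUR77 replicate 2 or GFP replicate 1, Sox9 without HA-NUR77 replicate 1 and Cebpa without GFP replicate 1. Thinned counts ended the calls of Csf1r (0.0698) and Pparg (0.0616), and no filter that of Tubb3 (0.0693).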

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

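Length and GC correction, with and without the block, and thinned counts were tests chosen after the results were seen. With the replicate number as a block there were 2942 genes higher and 3071 lower, with length and GC correction and the block 3070 and 2795, and at an adjusted p under 0.01 there were 447 and 653. Leaving out 1 library, which also lowers power, gave 642 to 1489 higher and 850 to 1572 lower. The other 11 of 14 settings kept both counts within 1.5 times, and DESeq2 called 3037 of the 3204 genes in the same direction. The OXPHOS list had an adjusted p of 0.65 with an estimated correlation. For the 88 named genes past the threshold, 1670 comparisons with alternatives all kept the direction and 1630 the threshold. These genes had passed in the same libraries, so a kept direction was largely fixed by the choice and gives no separate support for the calls. The block ended 1 of these calls, that of Bst2 (0.108), added Cldn5 and Krt19, and changed no other call of a gene taken by the naming rule. Among the members named besides, it ended those of Xaf1 and Rtp4 and added mt-Nd5, mt-Atp8, mt-Cytb, Yme1l1, Dnm1l, Mmp2 and Runx2.

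Some results that had not passed the threshold turned in sign, and the cause was not tested. Adjusted p after a turn was 0.999 (CPM of at least 1) and 0.941 (block) for the NR4A list and 0.843 (block) and 0.985 (thinned) for the p53 list. With length and GC correction it was 0.926, and 0.981 with the block too, for the mtDNA and the antioxidant lists. Leaving out 1 library, adjusted p ranged over 0.801 to 0.975 for the NR4A list, 0.787 to 0.909 for p53, 0.353 to 0.973 for mtDNA and 0.59 to 0.975 for biogenesis. Log2 fold changes ranged over −0.082 to 0.44 for Nr4a1, −0.37 to 0.012 for Nr4a3, −0.38 to 0.056 for Ppargc1a and −0.14 to 0.028 for mt-Co1.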

Other observations

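Families of genes that share a symbol stem gave further groups in which falls outnumbered rises, and all tests in this paragraph were chosen after the results were seen. Of 18 protocadherin beta genes, which encode cell adhesion proteins and lie in a cluster on chromosome 18, 15 fell and 0 rose, among them Pcdhb2 (log2 fold change −2.09), Pcdhb9 (−1.52) and Pcdhb16 (−0.52), with edgeR adjusted p of 0.00144, 0.00168 and 0.00218. Of 14 Adamts metalloproteases, 9 fell and 1 rose (median −0.89), or 10 and 3 of 19 (median −0.38) with the Adamtsl genes, and of 330 zinc finger genes with the stem Zfp, 60 fell and 7 rose (median −0.22), including Zfp521 (−1.56, adjusted p = 0.00114). Of all 12509 genes tested, 1655 fell and 1549 rose. With correction for length and GC content, 53 Zfp genes fell and 9 rose (median −0.165). With it 14 Pcdhb genes fell and 0 rose (median −0.66), and 9 Adamts and Adamtsl genes fell and 3 rose (median −0.32). Camera adjusted over 148 families gave 4.54e-07 for Pcdhb, 4.59e-11 for Adamts and 0.00174 for Zfp, and adjusted p = 0.777, 0.261 and 0.777 with an estimated correlation. Among 2380 windows of 30 neighbouring genes, 7 had a median beyond those of 200 shuffled orders (−0.43 to 0.35). These windows lay on chromosome 13 from 64189268 to 70841811 (40 genes, 20 of them Zfp, 13 lower and 0 higher) and on chromosome 18 from 36559987 to 39519421 (45 genes, 21 of them protocadherins, 16 lower and 1 higher; GRCm38).

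Apart from the splits, set before the data were examined, the tests in the following paragraphs were chosen after the results were seen. Among the 10 ways to part the 6 libraries into 3 and 3, only 1, the labelled one, called any gene by edgeR, 3204 against a highest other of 0, and 1 gave any gene changed at least 2-fold, 732 against 0. Each other split has both constructs on each side, so the difference between constructs adds to the spread within sides and lowers the calls. The 0 is therefore not the count expected without a difference. The other splits had 17 to 1055 genes at an unadjusted p under 0.05; DESeq2 and limma-voom were not run on them. As small a camera p for the OXPHOS list came from 2 of the 10, the labelled one (3.86e-15) and HA-NUR77 1 with GFP 1 and 2 (2.99e-16), which does not part all 3 pairs of same-numbered libraries. Of the other splits that part all 3, the smallest was 4.50e-10. The split of HA-NUR77 1 with GFP 1 and 2 has HA-NUR77 2 and 3 on its other side, so it holds part of the difference between constructs. With 10 splits no share can be under 0.05.

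OXPHOS subunits were higher in the libraries labelled HA-NUR77 by a median log2 of 0.33, and 3 technical or biological explanations were tested besides the splits. With the trend with transcript length and GC content removed, the median was 0.23 (bootstrap 95% interval 0.20 to 0.27), with 35 members higher, so part of the rise in these libraries remained. The interval resampled the members, which vary together, and not the dishes, so it does not cover variation between dishes. Depth does not account for the rise, with 51 members higher after thinning against 52 before. The state that separates libraries 2 and 3 moved the list opposite to the cell cycle list, by −0.11 in HA-NUR77 and −0.14 in GFP, against 0.40 and 0.68 for the cell cycle. Read as library 3 against 2, however, the OXPHOS, muscle, matrix and SRF lists moved as in HA-NUR77 against GFP. Library 2 minus 3 was −0.24 and −0.32 for muscle, 0.35 and 0.21 for matrix and 0.52 and 0.34 for SRF targets. The cell cycle, interferon, cholesterol and cytosolic ribosomal lists moved the other way, so this comparison does not decide on the state. Adjusted p over the alternatives ran from 4.25e-20 (no filter) to 0.65 (estimated correlation). A difference between the stable lines other than the construct stays open, as the labels give 1 line per construct, and a candidate explanation by NUR77 itself cannot be told apart from it.

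Mouse Nr4a1 was not past the test in the libraries labelled HA-NUR77. A single wrong label is argued against by the correlations of log2 CPM, at least 0.986 within a group and at most 0.973 between groups. A swap of whole groups was not tested. Reads of the construct may not be counted at the mouse gene, for instance if the insert is from another species. The upper 95% bound of a 1.64-fold change covers reads counted at the mouse gene only, so it cannot decide this. A construct that was little induced at the RNA level is not excluded by these counts either.

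Libraries with the same replicate number deviated together, with correlations of 0.25, 0.55 and 0.47. Depth is argued against, since the lowest was still 0.232 after thinning. Growth state of the dishes is a candidate explanation: between libraries 2 and 3 the cell cycle list differed by a median log2 of 0.40 in HA-NUR77 and 0.68 in GFP, against 95% of matched random lists within −0.11 to 0.07 and −0.10 to 0.09, and the muscle list by −0.24 and −0.32. Such random lists were matched on length, GC content and level, not on how genes vary together. The OXPHOS list also lay beyond its own, at −0.11 and −0.14 against −0.05 to 0.06 and −0.04 to 0.06. The difference was not specific to growth, with interferon-stimulated genes at 1.57 and 0.29, cholesterol genes at 0.78 and 0.43 and SRF targets at 0.52 and 0.34. A shared day of culture or library preparation, which the labels do not give, stays open. So does a match by chance, since 3 libraries per group can be matched in few ways.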
